A study of Mus musculus with 4 samples.

How the data were processed

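Total RNA was taken with TRIzol from primary mouse cortical culture after knockdown of CTCF or of lacZ by adeno-associated virus, per the labels' protocols. Fragments of about 300 bp were sequenced as paired reads of 101 bp on an Illumina HiSeq instrument. The 4 libraries were grouped by their labels into shCTCF and shLAC, with 2 replicates each. No label says whether the replicates came from separate cultures, so p-values rest at most on the spread between these libraries, which may be technical.

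The deposited files held TPM, a length-corrected share of transcripts, per Ensembl gene, 1 file per library, with 37437 genes and 2 decimals, and each file summed to 1000000. RSEM 1.2.28, CASAVA and the mm10 build are named in the submitters' processing notes. The annotation release, the aligner settings and the strandedness are not given in the sources used here. TPM divides estimated reads by gene length and by a total over all genes, so abundant RNA in 1 library lowers every other gene there, genes near or below the fragment length are estimated poorly, and depth is lost. Before the data were examined, the design provided for a count test or, if the files held normalized values, for limma; the values were TPM, so limma was used and tools that need counts were not run. Gene names, positions and biotypes came from GENCODE vM21 on GRCm38, the same assembly as mm10, which matched 37060 of 37437 identifiers. Antisense and overlapping genes cannot be separated where strand was not used.

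Genes with at least 1 TPM in at least 2 libraries were tested (12816), on log2(TPM + 1), with limma 3.58.1 in R 4.3.3, a trended prior, no covariate and Benjamini-Hochberg adjustment at 0.05. Fold changes are on this scale, which understates those of low genes. Median-ratio scaling of the deposited values was planned as an alternative and is printed beside them. After the data were seen, a fit on 11268 protein-coding genes of at least 300 nt after median-ratio scaling was added, without the 13 satellite-like predicted genes. Its changes are those called scaled, with standard errors and adjusted p of that fit unless stated. As deposited, limma's prior had infinite degrees of freedom. Each gene's variance there was that of the trend over genes, so its standard error and p do not measure the gene's own spread. The prior had 2.44 degrees of freedom in the scaled fit over all tested genes and 4.65 in the coding fit, where a gene's own spread counted.

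The genes named were fixed by a rule before the data were examined. It took Ctcf and, per direction, the 12 genes with the largest log2 fold change among those with adjusted p below 0.05, with both shCTCF values beyond both shLAC values and a mean of at least 2 TPM, leaving out predicted loci. As deposited, 111 higher and 34 lower genes met it. The same rule was applied to the coding fit, which was added later. For each list it took up to 4 called members, or the 2 with the highest mean where none was called; other called members named were chosen after their values were seen, as were the members of the cohesin list named. Some genes that the rule or a list would name are not reported here.

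29 gene lists were fixed before the data were examined, and 24 had at least 5 tested members. They were tested with limma's camera at a preset correlation of 0.01, adjusted over lists, and with an estimated correlation and fry as alternatives. The lists covered cohesin and CTCF partners, clustered protocadherins, other cadherins, synaptic adhesion, immediate early genes, plasticity genes, glutamate and GABA receptors, postsynaptic scaffold, synaptic vesicle genes, voltage-gated channels, p53 targets, interferon-stimulated genes, MHC class I, imprinted genes, Hox genes, stress response, cholesterol synthesis, mitochondrially encoded, nuclear respiratory chain and ribosomal protein genes. Further lists held markers of excitatory and inhibitory neurons, astrocytes, oligodendrocyte lineage, microglia, endothelium, fibroblasts and proliferating cells.

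Alternatives were other scalings, filters, pseudocounts and thresholds, a replicate block, and each library left out in turn, where a group of 1 library is taken to vary like the other group. The fits were tested on simulated values with 200 changed genes. With equal library scale, 0%, 47.0% and 96.5% of genes changed 1.5-fold, 2-fold and 4-fold were recovered among 12816 genes, with 0, 2 and 5 false calls. With the library scale of the deposited values, 5.00%, 54.5% and 99.5% were recovered with 13, 25 and 52 false calls, of which 12, 23 and 50 were higher. In the 11268 coding genes, simulated with equal library scale, 97.5%, 100% and 100% were recovered, with 29, 16 and 22 false calls. A simulated shift of the glutamate receptor list by -0.3 log2 units was recovered by camera with 0 other lists called of 24. Some lists called in the data moved less, such as synaptic vesicle genes with a median scaled change of 0.08. The correlations estimated as deposited lay from 0.217 to 0.962, far above the preset 0.01. They rest on 4 libraries, and the lower scale of shLAC replicate 2 moved most genes together. A call missed with them as deposited therefore does not show that a list stayed unchanged.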

Results

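RNA was measured in primary mouse cortical culture, in which cells were infected with adeno-associated virus that knocked down either Ctcf or, as control, lacZ, a bacterial gene with no mouse counterpart. CTCF is a zinc finger protein that binds insulator sites and, with cohesin, holds chromatin loops. The comparison asked which transcripts differed in level between CTCF knockdown (shCTCF) and the lacZ control (shLAC), with 2 libraries per group. Each library held TPM values for 37437 Ensembl genes, of which 12681 and 12189 reached 1 TPM in the shLAC libraries and 12839 and 12736 in the shCTCF libraries. TPM keeps no sequencing depth, so the depth of each library is unknown and no counting interval is given.

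Ctcf itself was lower in both knockdown libraries. Ctcf (ENSMUSG00000005698, protein-coding, chromosome 8, 105636568 to 105682922, + strand, GRCm38) was at 8.49 and 7.32 TPM in the shLAC libraries and at 3.56 TPM in each shCTCF library. The shCTCF mean was 45.0% of the control mean, or 39.1% after median-ratio scaling. The log2 fold change was -0.96 (SE 0.196, limma adjusted p = 7.11e-05, n = 2 per group) and -1.13 after scaling (SE 0.0617, limma adjusted p = 0.0177 over all tested genes; SE 0.0659, limma adjusted p = 0.00233 in the coding fit). Both shCTCF values lay below both shLAC values, and the smallest 2-sided p that an exact permutation test of 2 against 2 libraries allows is 0.333. The call was lost with no expression filter (limma adjusted p = 0.459) and when shLAC replicate 2, shCTCF replicate 1 or shCTCF replicate 2 was left out (limma adjusted p = 0.106, 1 and 0.983), with Ctcf lower in each. After scaling it was lost without the same 3 libraries (limma adjusted p = 0.0650, 0.121 and 0.109), and in the coding fit it held without each of the 4 (limma adjusted p up to 0.0476).

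**Figure D1:**
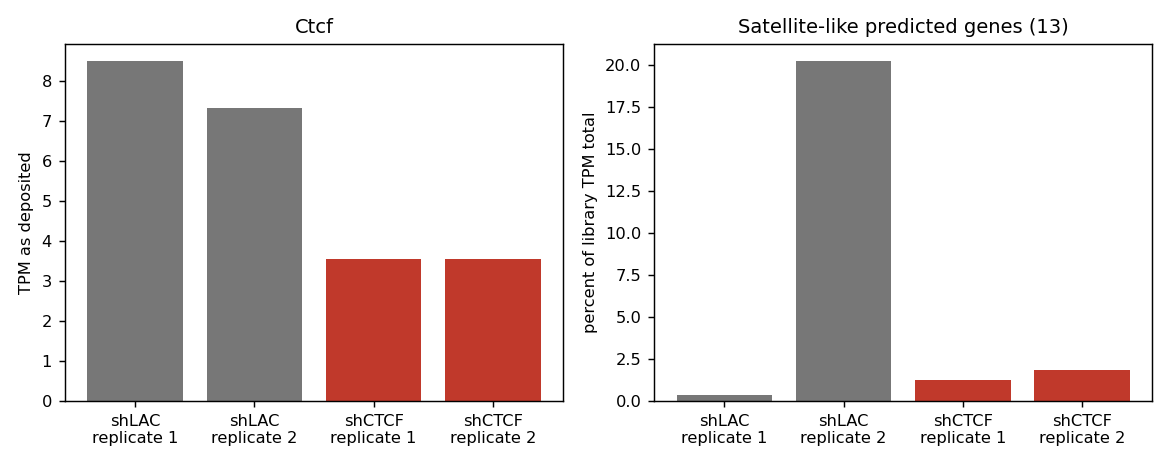
Bars give 1 value per library, with shLAC in grey and shCTCF in red. Left, Ctcf in TPM as deposited, at 8.49 and 7.32 in shLAC and 3.56 in both shCTCF libraries. Right, the percent of each library's TPM total in 13 satellite-like predicted genes, at 20.2% in shLAC replicate 2 and between 0.405% and 1.86% in the others.

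One control library stood apart. In shLAC replicate 2, 13 satellite-like predicted genes on chromosomes 2, 9 and 14, among them Gm10719 and Gm10800, held 20.2% of all TPM, against 0.405% in shLAC replicate 1 and 1.29% and 1.86% in the shCTCF libraries. Gm10719 was at 46642 TPM there and at 948 TPM in shLAC replicate 1. Because TPM sums to a fixed total, the other genes of that library were lower, and the median log2 fold change of the 12816 tested genes was 0.17 in the values as deposited. Changes are therefore given relative to this shift, after median-ratio scaling, beside the values as deposited. The small RNA genes Rn7s1, Rn7s2 and Rn7sk held between 30.9% and 40.8% of TPM and the mitochondrial ribosomal RNA genes between 17.0% and 20.2%. Across 11291 tested protein-coding genes, log2(TPM + 1) correlated at r = 0.9858 between the shLAC libraries and at r = 0.9963 between the shCTCF libraries. This set kept satellite-like genes of that biotype, such as Gm10719. Between groups r lay from 0.9858 to 0.9914, so on this set the shLAC libraries were no closer to each other than to the shCTCF libraries. How far the satellite-like genes lowered the r of the shLAC pair was not computed, and genes are not independent replicates.

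In the values as deposited, 246 genes rose and 116 fell in CTCF knockdown at a limma adjusted p below 0.05, so that 68.0% of the 362 calls were higher. After median-ratio scaling, 47 rose and 87 fell, and 35.1% of the 134 calls were higher; 36 of the higher and 35 of the lower calls were shared with the values as deposited. Genes shorter than 300 nt gave 153 of the 362 calls. Among the 11268 protein-coding genes of at least 300 nt, scaled and fitted alone, 272 rose and 402 fell. That fit was chosen after the data were seen. Leaving out shLAC replicate 1 gave 4665 higher and 135 lower genes as deposited, and leaving out shLAC replicate 2 gave 7 and 12. The coding-gene counts became 3 higher and 8 lower without shCTCF replicate 1, and 2 and 4 without shCTCF replicate 2.

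The coding genes that rose most after scaling were led by Mnd1, a meiotic recombination factor, which went from 0.56 ± 0.127 TPM to 6.19 ± 0.516 TPM (mean ± SD, n = 2). Its scaled log2 fold change was 2.08 (SE 0.0735, limma adjusted p = 3.92e-04). Ndrg1, a stress-responsive gene, rose by 1.36 (SE 0.148, limma adjusted p = 0.00646), from 3.51 ± 0.417 to 12.1 ± 1.07 TPM. Mettl25, a putative methyltransferase gene, rose by 1.26 and Zdhhc1, which encodes a palmitoyltransferase, by 1.10 on the log2 scale. Asl, the argininosuccinate lyase of the urea cycle, rose by 1.09, and Fuz, which acts in ciliogenesis, by 1.01. Sun2, a nuclear envelope protein that links to the cytoskeleton, rose by 0.89, Plcxd2 by 0.80 and Rasal1, a Ras GTPase-activating protein, by 0.77. Gpc5, a heparan sulfate proteoglycan, rose by 0.71, Epas1, a hypoxia-inducible transcription factor, by 0.68 and Hspa1a, an inducible heat shock protein, by 0.67. The limma adjusted p of these genes in the coding fit reached 0.0288, in Hspa1a, whose reads are shared with a near-identical neighbouring paralog, so that its level is uncertain. Over all tested genes after scaling, Ndrg1 (limma adjusted p = 0.0610), Rasal1 (0.0703), Gpc5 (0.0629), Epas1 (0.0745) and Hspa1a (0.112) did not pass.

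The coding genes that fell most were led by Hmox1, the inducible heme oxygenase, which went from 14.8 ± 5.76 to 4.43 ± 1.32 TPM. Its scaled log2 fold change was -1.69 (SE 0.184, limma adjusted p = 0.00646). Bola3, which acts in mitochondrial iron-sulfur cluster assembly, fell by 1.14 (SE 0.101, limma adjusted p = 0.00449). Ppa2, a mitochondrial pyrophosphatase, fell by 1.13 and Mrpl23, a mitochondrial ribosomal protein, by 1.09 on the log2 scale. Mdp1, a phosphatase gene, fell by 1.09, and Aqp4, the water channel of astrocytes, by 1.08. Mus81, a structure-specific endonuclease of DNA repair, fell from 3.30 ± 0.679 to 1.34 ± 0.113 TPM, and the activity-regulated gene Arc fell by 0.99 on the log2 scale. Kcnf1, a potassium channel subunit, fell by 0.95, Gabra5, a GABA receptor subunit, by 0.92 and Bak1, a pro-apoptotic protein, by 0.91. With Ctcf these made 12 genes, all of which also fell in the values as deposited. Over all tested genes after scaling, Hmox1 (limma adjusted p = 0.0619), Aqp4 (0.0858), Arc (0.129) and Kcnf1 (0.0745) did not pass. Of the coding genes, 240 that rose and 341 that fell met the same conditions on level and separation.

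**Figure D2:**
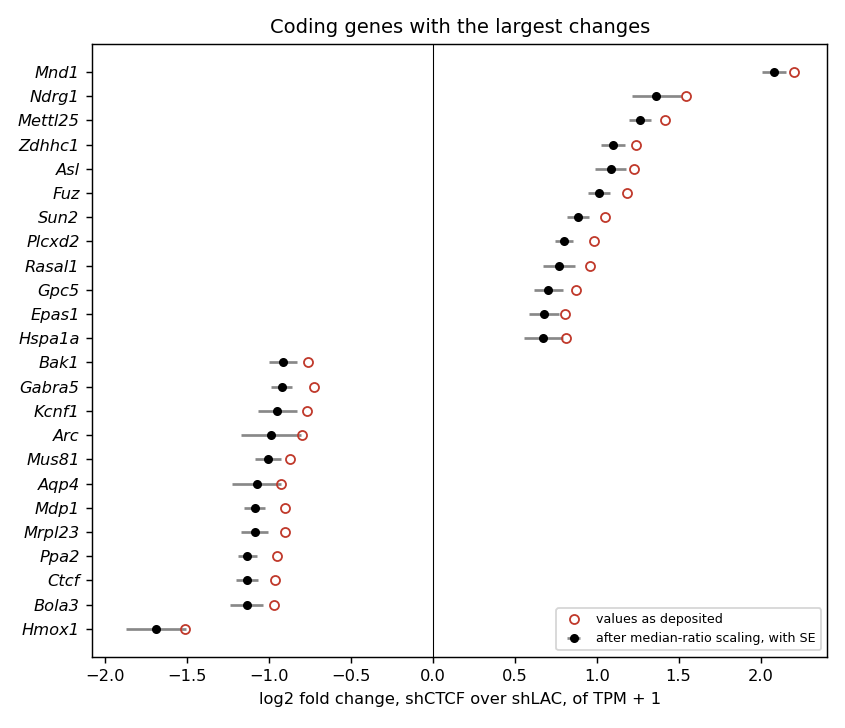
Log2 fold changes of TPM + 1, shCTCF over shLAC, of the 24 coding genes named by the rule, 12 in each direction. Black points with bars give the value after median-ratio scaling and its standard error, and red circles the value as deposited; the scaled values lie lower in every gene, from 2.08 in Mnd1 to -1.69 in Hmox1.

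Short noncoding genes filled most of the places when the rule was applied to all genes as deposited. Snora78, a small nucleolar RNA, went from 47.3 and 21.4 TPM in shLAC to 126 and 171 TPM in shCTCF, with a log2 fold change of 2.17 (SE 0.235, limma adjusted p = 5.81e-18). Behind it stood 10 copies of the 5S ribosomal RNA gene on chromosome 8, among them n-R5s124, with identical values of 1.95 and 1.57 TPM in shLAC and 16.9 and 5.28 TPM in shCTCF. These copies share reads, so they are uncertain as single genes. Their standard error was 0.190 as deposited, taken from the trend over genes, and 0.489 after scaling, where their own spread counted. Another copy, n-R5s136, was at 15.6 and 12.6 TPM in shLAC and listed at 0 in both shCTCF libraries, as were Mir1188 (13.9 and 11.2 TPM), Snora30 (5.84 and 4.61 TPM) and Snora16a (7.98 and 3.12 TPM). After scaling, Snora78 (limma adjusted p = 0.0857) and the 10 copies (limma adjusted p = 0.167) no longer passed, while n-R5s136 and Mir1188 (limma adjusted p = 3.07e-04 each), Snora30 (0.00105) and Snora16a (0.0490) did.

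The clustered protocadherins, neuronal adhesion proteins encoded by 3 gene arrays on chromosome 18, were mostly lower. Of 52 tested members, 46 had a negative scaled log2 fold change, with a median of -0.34. In the coding fit, 26 fell, 1 rose and 25 did not pass, and adjusted over the list alone 39 fell and 3 rose. After scaling, 5 fell and 0 rose over all tested genes, and 37 fell and 3 rose adjusted over the list alone. As deposited, 6 fell over all genes tested, and adjusted over the list alone 13 fell and 2 rose. In the coding fit the calls were lost without either shCTCF library. As deposited and after scaling they were lost without shLAC replicate 2 or either shCTCF library. With 1 library left out, from 37 to 46 of 52 members were lower as deposited. After scaling and in the coding fit, from 45 to 47 were lower. All 21 tested Pcdhb genes were lower, and their summed scaled TPM went from 47.7 ± 1.62 in shLAC to 27.8 ± 1.39 in shCTCF (mean ± SD, n = 2), 58.2% of control. The Pcdha sum went from 33.2 ± 2.50 to 29.7 ± 1.84 and the Pcdhg sum from 97.1 ± 0.0191 to 86.8 ± 1.04, each 89.4% of control. Pcdhb9 went from 4.63 ± 0.354 to 2.40 ± 0.170 TPM, a scaled log2 fold change of -0.88 (SE 0.0759, limma adjusted p = 0.00427). Pcdhb13 fell by 0.56 (limma adjusted p = 0.0150) and Pcdhb12 by 0.61 (limma adjusted p = 0.0112). Pcdhac2, at the end of the Pcdha array, rose by 0.37 (SE 0.0543, limma adjusted p = 0.0156). Pcdha4 fell in the values as deposited (log2 fold change -0.74, limma adjusted p = 9.82e-05) and had a limma adjusted p of 0.0547 in the coding fit.

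The list was called lower by limma's camera with a preset correlation, with adjusted p = 6.34e-16 as deposited and 8.81e-16 in the coding fit. With an estimated correlation, adjusted p = 0.998 as deposited and adjusted p = 0.721 in the coding fit, and no list was called in any fit. Among the 5 members with a mean of at least 5 TPM the direction was upward and the call was lost (adjusted p = 0.754). Of these 5, 0 were Pcdhb genes, so the Pcdhb decrease was not examined at that level. Pcdha and Pcdhg genes share their constant exons, so the division of reads among them is uncertain.

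**Figure D3:**
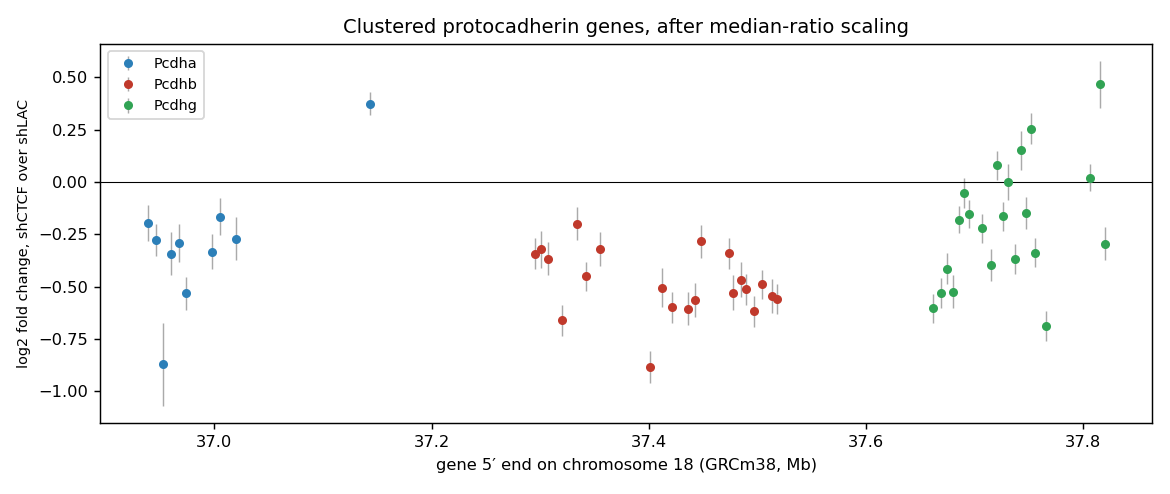
Scaled log2 fold change, shCTCF over shLAC, of the 52 tested clustered protocadherin genes against the 5′ end of each gene on chromosome 18 in Mb. Points are coloured by array (Pcdha, Pcdhb, Pcdhg) and bars give the standard error; all 21 Pcdhb points lie below 0, and Pcdhac2 lies at 0.37.

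Among immediate early genes, which neuronal activity induces within minutes, 3 fell in the coding fit and the list was called lower with all 4 libraries. Of 26 tested members, 22 had a negative scaled log2 fold change, with a median of -0.19. In the coding fit Arc, Egr2 and Egr1 fell and 23 did not pass, and adjusted over the list alone 3 fell and 1 rose. Arc went from 22.9 and 11.5 TPM in shLAC to 8.72 and 9.09 TPM in shCTCF (scaled log2 fold change -0.99, SE 0.184, limma adjusted p = 0.0323). Egr2 fell by 0.83 (SE 0.107, limma adjusted p = 0.0106) and Egr1 by 0.54 (SE 0.114, limma adjusted p = 0.0456). As deposited 2 fell, and 2 fell adjusted over the list alone. Over all tested genes after scaling, 0 passed, and adjusted over the list alone 1 fell. Camera called the list lower as deposited (adjusted p = 5.53e-04) and in the coding fit (adjusted p = 0.00419), and with an estimated correlation adjusted p = 0.998 and adjusted p = 0.820. Without shLAC replicate 1 the call was lost, with adjusted p = 0.0714 as deposited and 0.434 in the coding fit.

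Among astrocyte markers, 2 fell in the coding fit and the list was called lower with all 4 libraries. Of 18 tested markers, 14 had a negative scaled log2 fold change, with a median of -0.23. Aqp4 went from 4.57 ± 1.53 to 1.91 ± 0.629 TPM (scaled log2 fold change -1.08, SE 0.152, limma adjusted p = 0.0144), and Slc1a3, the glial glutamate transporter, fell by 0.52 (limma adjusted p = 0.0195). Slco1c1 fell in the values as deposited (log2 fold change -0.58, limma adjusted p = 0.0311) and did not pass in the coding fit (limma adjusted p = 0.0612). In the coding fit 2 fell and 16 did not pass, and 3 fell adjusted over the list alone. As deposited 2 fell by both adjustments. Over all tested genes after scaling, 0 passed, and adjusted over the list alone 2 fell. Camera gave adjusted p = 0.00368 as deposited and 0.0231 in the coding fit, and with an estimated correlation adjusted p = 0.998 and adjusted p = 0.820. The call was lost without shCTCF replicate 2 (adjusted p = 0.971 as deposited, 0.449 in the coding fit), in the coding fit without shLAC replicate 1 (adjusted p = 0.204), and at a mean of at least 5 TPM (adjusted p = 0.453).

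Lists of other cell type markers were not called as deposited, after scaling or in the coding fit. None of the 15 excitatory neuron markers passed in the coding fit (4 rose and 3 fell adjusted over the list alone), and Slc17a7, a vesicular glutamate transporter, was at 67.6 ± 15.9 TPM in shLAC and 91.8 ± 6.75 TPM in shCTCF (limma adjusted p = 0.0807); camera adjusted p was 0.990. In the coding fit, Slc32a1, the vesicular GABA transporter, rose by 0.36 and Calb2 fell by 0.23 among 19 inhibitory neuron markers. Adjusted over the list alone 2 rose and 2 fell (camera adjusted p = 0.294). Over all tested genes, 0 inhibitory markers passed as deposited or after scaling. None of 11 oligodendrocyte lineage markers, such as Olig1 (30.5 ± 8.73 and 37.3 ± 3.03 TPM), passed over all genes or adjusted over the list alone (camera adjusted p = 0.764). None of 21 proliferation and progenitor markers, such as Vim (41.5 ± 8.54 and 53.2 ± 1.99 TPM), passed by either adjustment (camera adjusted p = 0.327). Of microglial markers 2 were expressed, among them Cd68, and neither passed. Of 4 fibroblast markers Dcn fell by 0.49 in the coding fit (limma adjusted p = 0.0209), and it also fell adjusted over the list alone. Over all tested genes, 0 fibroblast markers passed as deposited or after scaling. At an unadjusted p below 0.05 after scaling, 7 excitatory, 1 oligodendrocyte, 2 proliferation and 0 microglial markers differed. No endothelial marker and no Hox gene reached the expression filter. Proliferation markers were called higher in the coding fit without shLAC replicate 2 (camera adjusted p = 0.0367); with no filter they (0.0113) and inhibitory markers (0.0183) were called higher, and endothelial markers (0.0359) and Hox genes (1.48e-04) lower. With an estimated correlation none of these calls held (adjusted p = 0.773 and, with no filter, 0.926).

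Among genes of the synaptic vesicle and release machinery, 4 rose in the coding fit. Over all tested genes, 0 passed as deposited or after scaling, and adjusted over the list alone 0 and 2 rose. Of 34 tested members, 23 had a positive scaled log2 fold change, with a median of 0.08. Syn1, a vesicle phosphoprotein, rose by 0.29 (SE 0.0499, limma adjusted p = 0.0242), Rims3 by 0.36 and Slc32a1 by 0.36. In the coding fit 30 did not pass, and adjusted over the list alone 9 rose and 2 fell. Camera called the list higher after scaling (adjusted p = 0.00810) and in the coding fit (adjusted p = 0.00419), but not as deposited (adjusted p = 0.642), where it was called without shLAC replicate 1 (0.00150) or shLAC replicate 2 (0.00751). With an estimated correlation these calls were lost, with adjusted p = 0.740 after scaling, 0.721 in the coding fit, and 0.933 and 0.980 as deposited without shLAC replicate 1 and 2.

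Other synaptic and membrane genes moved in both directions in the coding fit, to which the calls named here belong. Over all tested genes, 0 adhesion, scaffold and non-clustered cadherin genes passed as deposited or after scaling. Of channel genes 1 rose as deposited and 1 fell after scaling. Of glutamate receptor genes 0 passed as deposited and 1 fell after scaling, and of plasticity genes 1 fell as deposited and 0 passed after scaling. Of GABA receptor genes 1 fell in both. Of 48 synaptic adhesion genes, Ncam2 (0.37), Tenm4 (0.34) and Nrxn2 (0.25) rose on the log2 scale, while Lrrtm4 (-0.52), Flrt3 (-0.49), Ncam1 (-0.49), Cntnap1 (-0.35) and Nlgn1 (-0.33) fell, and adjusted over the list alone 8 rose and 5 fell (camera adjusted p = 0.0837). Of 50 voltage-gated channel genes, the calcium channel genes Cacna1h (0.54), Cacna1a (0.35) and Cacna2d3 (0.29) and Kcnip4 (0.43) rose and Kcnh1 (-0.55) fell, and adjusted over the list alone 12 rose and 3 fell (camera adjusted p = 0.225). Of 28 glutamate receptor genes, the metabotropic receptor Grm5 (-0.31) and the kainate receptor subunit Grik4 (-0.47) were among those that fell, and Cacng8 (0.29) rose, with 3 higher and 4 lower adjusted over the list alone (camera adjusted p = 0.746). Gabra5 was the 1 of 16 GABA receptor genes that fell, also adjusted over the list alone, from 33.5 ± 7.40 to 19.7 ± 1.66 TPM (limma adjusted p = 0.00292, camera adjusted p = 0.447). Of 22 postsynaptic scaffold genes Dlg2 (-0.22) and Anks1b (-0.30) fell, and adjusted over the list alone 7 rose and 2 fell (camera adjusted p = 0.0837). Of 36 plasticity genes Arc and Rasgrf1 (-0.23) fell, and adjusted over the list alone 3 rose and 5 fell (camera adjusted p = 0.437). Of 24 non-clustered cadherins Pcdh20 (-0.57) and Cdh22 (-0.34) fell, and adjusted over the list alone 4 rose and 2 fell (camera adjusted p = 0.294). In the coding fit, the scaffold list was called higher without shLAC replicate 1 (camera adjusted p = 0.0167) and the adhesion list without shCTCF replicate 1 (0.0471), and with an estimated correlation neither was (adjusted p from 0.862). As deposited without shLAC replicate 1, the scaffold (0.0165) and channel (0.0466) lists were called higher. With no filter the adhesion and channel lists (0.00185 each), the scaffold (0.00624), plasticity (0.0291) and non-clustered cadherin (0.0375) lists were. With an estimated correlation none of these calls held (adjusted p from 0.926).

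Among 15 tested cohesin and CTCF partner genes, Stag1, a cohesin subunit, rose from 4.59 ± 0.714 to 8.64 ± 0.580 TPM, also adjusted over the list alone. Its log2 fold change was 0.79 as deposited (limma adjusted p = 0.00437) and 0.61 after scaling (SE 0.0600, limma adjusted p = 0.00496 in the coding fit). The related subunit Stag2 stood at a scaled log2 fold change of 0.01 (limma adjusted p = 0.949), Rad21 at 0.05 and the loading factor Nipbl at 0.04, none of which passed (camera adjusted p = 0.884 for the list). Of 28 imprinted genes tested, 19 had a positive scaled value; in the coding fit of 21 of them the potassium channel gene Kcnk9 rose by 0.51 (SE 0.0569, limma adjusted p = 0.00730), Sgce fell by 0.40 and Rasgrf1 by 0.23, and adjusted over the list alone 7 rose and 3 fell. Camera called the imprinted list higher after scaling (adjusted p = 0.0351) and in the coding fit (adjusted p = 0.0231), but not as deposited (adjusted p = 0.801). With an estimated correlation, adjusted p = 0.721 in the coding fit. The call was lost without shLAC replicate 1 (adjusted p = 0.283 after scaling, 0.128 in the coding fit), without shCTCF replicate 2 (0.124 and 0.0816) and, after scaling, without shCTCF replicate 1 (0.0586).

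Of 21 stress response genes, Slc7a11, a cystine transporter, fell by 0.95 and Mthfd2, a mitochondrial folate enzyme, by 0.88 in the coding fit. The same count fell adjusted over the list alone (camera adjusted p = 0.650). Over all tested genes, 2 fell as deposited and 1 after scaling. Of 22 p53 targets, Trp53inp1 (0.31) rose and Rprm (-0.67), Phlda3 (-0.43) and Ccng1 (-0.25) fell in the coding fit. Adjusted over the list alone there, 2 were higher and 3 lower (camera adjusted p = 0.990). Over all tested genes, 0 p53 targets passed as deposited and 1 fell after scaling. None of 7 MHC class I genes passed by either adjustment (camera adjusted p = 0.990), and of 4 interferon-stimulated genes none passed and 1 rose adjusted over the list alone. After scaling, 1 MHC gene, 1 interferon-stimulated gene and 0 mitochondrially encoded genes had an unadjusted p below 0.05. All 13 mitochondrially encoded genes had negative scaled log2 fold changes, with a median of -0.12 and none passing by either adjustment (camera adjusted p = 0.178 after scaling, 0.157 in the coding fit). Without shLAC replicate 1 that list was called lower (camera adjusted p = 0.0435 as deposited, 4.27e-05 after scaling, 1.72e-08 in the coding fit), and without shLAC replicate 2 its direction was upward and not called (0.398, 0.643 and 0.472). With an estimated correlation none of these 3 calls held (adjusted p from 0.844). In the coding fit, 5 of 71 nuclear respiratory chain genes fell, among them Ndufb7 (-0.41) and Ndufb10 (-0.27), and 5 fell adjusted over the list alone. As deposited and after scaling, 0 of them passed by either adjustment. The list was called lower after scaling (camera adjusted p = 0.0351, or 0.854 with an estimated correlation) but not in the coding fit (adjusted p = 0.0625). Of 81 cytosolic ribosomal protein genes Rpl36a (-0.34) and Rps4x (-0.33) fell in the coding fit, as did 2 adjusted over the list alone. As deposited and after scaling, 0 of the 81 passed by either adjustment. This list was also called lower after scaling (camera adjusted p = 0.0423, or 0.854 with an estimated correlation) but not in the coding fit (adjusted p = 0.0837). Without shLAC replicate 1, both lists were called higher as deposited (camera adjusted p = 0.00652 for the respiratory chain and 1.34e-04 for the ribosomal genes; with an estimated correlation, 0.933 for both) and neither was called after scaling (0.749 and 0.99987). The scaled calls were also lost without shCTCF replicate 1 (0.0820 and 0.309) and, for the respiratory chain, without shCTCF replicate 2 (0.104), whereas without shLAC replicate 2 both were called lower in the coding fit (9.32e-04 and 4.02e-04), with adjusted p = 0.773 under an estimated correlation. Of 20 cholesterol synthesis genes, 19 did not pass in the coding fit, and adjusted over the list alone 2 rose and 1 fell (camera adjusted p = 0.157). That list was called higher as deposited without shLAC replicate 1 (camera adjusted p = 0.0165; with an estimated correlation, 0.933) and with no filter (0.0107; 0.926).

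**Figure D4:**
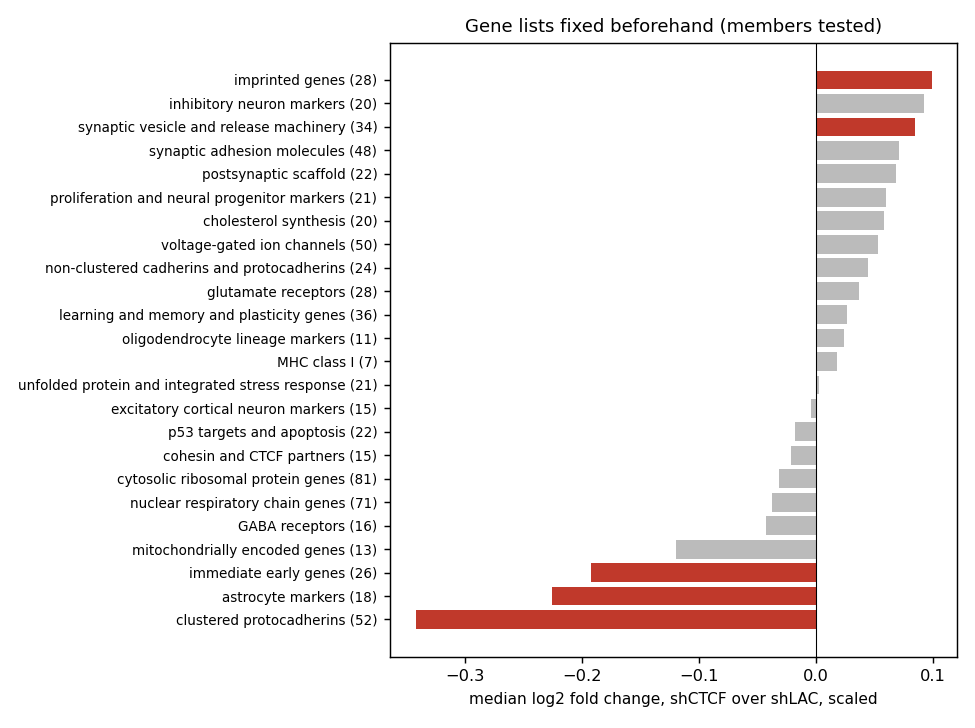
Median scaled log2 fold change, shCTCF over shLAC, of the tested members of each of 24 gene lists, with the number of members in parentheses. Red bars mark the 5 lists called by camera in the coding fit, from -0.34 in the clustered protocadherins to 0.10 in the imprinted genes; grey bars were not called.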

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

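The coding-gene fits, the fits without satellite-like genes, and the scaled fits with a block or a library left out were chosen after the data were seen. As deposited 362 genes were called (246 higher, 116 lower). The count moved to 134 (47 higher, 87 lower) with median-ratio scaling, 112 (38 and 74) with quantile normalization, 18 (10 and 8) with no filter, 138 (97 and 41) at a mean of at least 5 TPM, 92 (44 and 48) without satellite-like genes, 674 (272 and 402) in scaled coding genes and 165 (114 and 51) in coding genes as deposited. Leaving out 1 library gave from 19 to 4800 genes as deposited (7 to 4665 higher, 12 to 135 lower), and 101, 26, 9 and 54 after scaling on leaving out shLAC replicate 1, shLAC replicate 2, shCTCF replicate 1 and shCTCF replicate 2 (37, 9, 2 and 42 higher; 64, 17, 7 and 12 lower). In the same order, scaled coding genes gave 988, 978, 11 and 6 (433, 391, 3 and 2 higher; 555, 587, 8 and 4 lower). The extreme of 4800 came without shLAC replicate 1, when the control was shLAC replicate 2 alone, and that of 19 without shLAC replicate 2. The 11 and 6 calls came when the spread was that of the shLAC pair. With a pseudocount of 0.1 the count was 348. The Ctcf change was downward in each setting run. Its call was lost with no filter (-0.96, limma adjusted p = 0.459). On leaving out 1 library its log2 fold change lay between -0.87 and -1.06 as deposited, with the call lost in 3 of 4 fits, and at -1.10 (without shLAC replicate 2), -1.10 (without shCTCF replicate 1) and -1.15 (without shCTCF replicate 2) in the scaled fits that lost it; limma adjusted p reached 1. Camera called 3 lists as deposited, 7 after median-ratio scaling, 6 with quantile normalization, 15 with no filter, 1 at a mean of at least 5 TPM, 5 without satellite-like genes, 5 in scaled coding genes, and 0 with an estimated correlation or fry, where no list had an unadjusted p below 0.05 as deposited. After scaling, limma's fry had an unadjusted p below 0.05 for the clustered protocadherin, synaptic vesicle and inhibitory neuron lists. None of them passed adjustment over the lists (limma fry adjusted p from 0.0630). With camera, leaving out 1 library gave between 2 and 9 lists as deposited and between 4 and 7 after scaling. In coding genes it gave 4 to 8, with 8 without shLAC replicate 2 and 6 without shCTCF replicate 1. The log2 fold change of Tyms, a member of the proliferation and progenitor list, was 0.16 as deposited and -0.04 after scaling, each with all 4 libraries. It was -0.29 in scaled coding genes without shLAC replicate 1. Part of these shifts was a matter of library scale. The median log2 fold change of tested genes was 0.17 as deposited and 0.30 as deposited without shLAC replicate 1. Median-ratio scaling brought it to -4.44e-04 with all 4 libraries. Other causes were not tested beyond the fewer libraries or genes each setting holds. DESeq2, limma-voom and upper-quartile scaling of counts were not run, since the values were TPM. Depth is unknown, so what it limits cannot be stated.

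Replicate numbers are shared by the groups, but no label says that a number marks a shared culture, so the libraries were not paired. Deviations from the group means of same-numbered libraries correlated across genes at 0.0854 as deposited, 0.0817 after scaling and 0.246 in scaled coding genes. A replicate block gave 478 genes as deposited (346 higher, 132 lower), 14 after scaling (5 higher, 9 lower), with the Ctcf change at -1.13 and limma adjusted p = 0.0572, and 1105 in scaled coding genes (476 higher, 629 lower). With the block, 5 lists were called after scaling and 5 in coding genes.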

Other observations

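The tests of the share of TPM held by satellite-like genes, of neuron content and of the scaled receptor gene ratio were chosen only after the result was seen. The others, that of genomic DNA included, were written beforehand. Hypotheses raised by named genes were tested on lists without those genes. Of targets of the antioxidant regulator NRF2, Hmox1, Slc7a11, Gstm1 (-0.68) and Mgst1 (-0.64) fell and Prdx1 (0.47) rose in the coding fit. These 5 were left out of the test, and 25 other NRF2 targets had a median scaled log2 fold change of -0.03, with 16 lower. Limma's camera gave them an adjusted p = 0.614 over both lists (0.517 before adjustment). Ndrg1 and Epas1 rose, and both relate to hypoxia, but 25 other hypoxia genes had a median of -0.01, with 11 higher and 14 lower. Limma's camera gave these an adjusted p = 0.614 (0.614 before adjustment). Neither list was shown to shift, and a p that misses the threshold leaves a small shift open. Change did not follow gene length. The Spearman rho of genomic span and scaled log2 fold change across 11268 coding genes was 0.0403, and genes are not independent replicates. Scaled changes of 8184 adjacent coding gene pairs within 100 kb, clustered protocadherins left out, correlated at 0.0333. This lay below the highest of 100 random orders (0.0360) and the within-group value of the shCTCF pair (0.0629), but above that of the shLAC pair (0.0319). The condition set beforehand for a shared shift of neighbours was not met. Only the highest random order was kept, so a small shared shift stays open.

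More genes were higher than lower as deposited, and shLAC replicate 2 held 20.2% of its TPM in satellite-like genes. With those genes left out, its median-ratio factor rose from 0.832 to 0.977, which is consistent with their share of the fixed total as a source of part of the imbalance. Left out, 44 genes were higher and 48 lower at a limma adjusted p below 0.05, but at an unadjusted p below 0.05 there were 2036 higher and 726 lower, and the median log2 fold change was still 0.05. Genomic DNA in that library is a candidate source of the satellite-like signal. Olfactory and vomeronasal receptor genes (1320 listed) had a mean TPM 1.36 times that of the highest other library and 1.64 times that of shLAC replicate 1, or 1.73 and 2.05 times after median-ratio scaling, and 69.5% were above 0 there against at most 21.7% elsewhere. A deeper library raises the share of genes above 0 but not a share of TPM, so depth alone leaves the satellite-like signal unaccounted for. The ratio of 1.36 fell short of the 2 times over the highest other library set beforehand for genomic DNA, as did 1.73, without excluding it, so that source stays open, and no biological explanation was tested.

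Short noncoding genes gave many of the calls as deposited. Of 356 tested genes under 300 nt, 48.6% differed by more than 1 log2 unit between libraries of the same group, against 0.151% of 11268 coding genes, a ratio of 322. This is consistent with unstable TPM estimates for genes shorter than the sequenced fragments. An effect of CTCF knockdown on some of these RNAs stays open and untested.

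Of the 52 clustered protocadherins, 26 fell, 1 rose and 25 did not pass in the coding fit, and 0 were called without either shCTCF library. All 21 Pcdhb genes were lower. The list was not called with an estimated correlation (adjusted p = 0.998 as deposited and 0.721 in the coding fit). A different division of reads among paralogs would leave the summed Pcdhb level in place, but the sum in shCTCF was 0.582 of that in shLAC, lower in both libraries. Fewer neurons in the shCTCF cultures would lower neuronal genes together, but the synaptic vesicle list had a median scaled log2 fold change of 0.0843. Scaling centres the tested genes (median -4.44e-04), so a fall shared by most genes would be scaled away. The value therefore shows only that the vesicle genes did not share the scaled protocadherin fall, and neuron content itself stays open. An effect of the lower Ctcf itself, off-target effects of the knockdown construct, a batch that follows the groups, and the lower astrocyte markers beside them stay open and untested.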
